A study of Rattus norvegicus with 6 samples.

How the data were processed

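Gene expression was measured on 6 one-colour microarrays of adult male Sprague-Dawley rats. Of these arrays, 2 carried the pineal gland, and 1 each carried the subcommissural organ, the subfornical organ, the ependyma of the third ventricle and total brain. The subcommissural organ, the subfornical organ and the ependyma were each a pool of 2, with no word on what was pooled, and total brain was a pool that served as the reference, per the labels. The structures were cut out under a microscope with an infrared laser around the regions of interest, with photographs taken before and after, per the labels. The ependyma was sampled from the ventricular wall at a distance from the subcommissural and subfornical organs, per the labels. The labels name no marker gene used to choose the regions. From each sample, 3 ng of total RNA was amplified in 2 rounds of in vitro transcription, labelled with biotin and read in the Cy5 channel, with synthetic spike RNAs added before amplification, per the labels.

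The deposited table held 1 intensity per probe and array on a linear scale, as the authors processed it. The scanner, the software, the background correction and the scaling were not given in the sources used here. The array medians were 1.05 for both pineal gland arrays, 1.05 for the subcommissural organ, 1.04 for the subfornical organ, 1.06 for the ependyma and 1.07 for total brain. Medians this close to each other show that the arrays had been brought to a common centre, but the method stays unknown. The linear scale was read from the values, which had no stated scale, and small negative values were present. Direction is not in question, because each column is the level of 1 sample and not a ratio. A value of -9999 was taken as missing. Of 35129 probes, 34963 had a value on all 6 arrays and 166 lacked one on at least 1 array. No detection call was used here, so the limit of detection is unknown. The number of arrays limits the precision of every value.

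Probes were named through the platform annotation. A single gene symbol was listed for 16865 probes and several symbols for 165. The other 18099 probes were not listed and have no name here, which does not mean that they have no gene. The gene identifiers of 16836 probes were found in a current gene table, which updated 1 symbol. Values below 0.142, the pooled 5th percentile, were raised to it, and log2 was taken. No further scaling was applied. Each of 12167 genes was represented by the brightest of its probes, by the mean over the 6 arrays. Where another probe of a gene counted as 4-fold different was also measured, it lay on the opposite side of 0 for 51 of 321 such genes in pineal gland against total brain, and for 23 of 146 in subcommissural organ against ependyma. Against total brain it did so for 54 of 367 in the subcommissural organ, 51 of 251 in the subfornical organ and 50 of 241 in the ependyma. Against the ependyma it did so for 23 of 253 in the pineal gland and 23 of 143 in the subfornical organ.

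A gene counted as measured in a comparison when the higher side reached 1.05, the pooled 50th percentile. Differences of at least 4-fold were counted without a test where a side had 1 array. For the pineal gland the mean log2 of its 2 arrays was used, and both arrays had to lie on the same side. Where the lower side of a fold was under 1.05, the fold is a bound against that value, written as at least so many fold. This bound was chosen after the data were examined. A gene marked a structure when it was at least 4-fold above each other tissue. For this the lower of the 2 pineal gland arrays was used for the gland itself, and the higher of them when another structure was set against it.

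Both comparisons of the pineal gland with a single array, total brain or ependyma, were also tested with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The fit held all 6 arrays with a mean per tissue. Its only residual degree of freedom, 1, came from the pineal gland pair, and the lone array on the other side was assumed to vary like that pair. Nothing in the labels says whether the 2 pineal gland arrays came from separate animals, so the p-values measure only the spread between these 2 arrays, which may be technical. The moderated spread came out the same for every gene, with a standard error of 0.72 on the log2 scale in both comparisons, so a call was in effect a minimum size of 1.82 against total brain and 1.85 against the ependyma. After quantile normalization, and without the filter on low values, the spread differed between genes, so calls there followed another rule. The other comparisons have 1 array on each side, and their differences have no replicate check.

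Before the data were examined, 20 gene lists, the size of 4-fold, the filter, the tests and the alternatives were fixed. The lists covered melatonin and serotonin synthesis, phototransduction, pineal transcription factors, the adrenergic and cAMP response of the pineal, the roof plate and subcommissural organ, the secretory machinery of the endoplasmic reticulum, and the body fluid and hormone receptors of the subfornical organ. Other lists held the blood-brain barrier, immediate early and stress genes, and housekeeping genes. Markers covered motile cilia, tanycytes, choroid plexus, neurons, oligodendrocytes, astrocytes, microglia and macrophages, endothelium, mural cells and fibroblasts, and the habenula. They comprised 337 different genes, of which 269 were on the array. Each list was described by the median log2 difference of its measured genes, with the percentile of that median among 10000 random lists of the same size matched on mean level. The percentile describes these arrays and is not a test of the tissues.

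Genes were named by a rule. For each comparison it took the 10 largest differences in each direction among those at 4-fold, and up to 4 measured members of each list with the largest differences. For each structure it took the 12 genes with the largest margin above every other tissue. The differences were ranked after the floor was set, so the order of genes near background carries no meaning. Symbols beginning with LOC, RGD or MGC and open reading frame names were counted but passed over in naming. Genes named outside the rule are marked as chosen after their values were seen.

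The alternatives were quantile normalization of the 6 arrays, no filter on low values, a filter at the 75th percentile (6.04), the mean of a gene's probes, a size of 2-fold, a floor at the 20th percentile, an intensity trend in eBayes, limma over all 6 arrays for the lone-array comparisons, and each pineal gland array left out in turn. A floor at the 50th percentile was added after the data were examined.

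The procedure was tested on simulated data for 12167 genes, with 50 genes set at each fold and the spread of the pineal gland pair but no offset between its arrays. With 2 arrays against 1, limma called 20.0% of the genes set at 4-fold, 84.0% at 8-fold and 98.0% at 16-fold, and 11 unchanged genes. With the offset between the pineal gland arrays put in, limma took in 53 unchanged genes. In both simulations 11967 genes were unchanged, and the changed ones were all above the bound in total brain. In the data limma called 2160 genes in the pineal gland against total brain. The cut after adjustment depends on how many genes differ, so these limma rates do not describe the calls in the data. The count at 4-fold recovered 50.0% of genes truly at 4-fold with 2 arrays against 1 and 56.0% with 1 against 1. It took in 104 and 181 unchanged genes in these settings. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.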

Results

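The data describe the pineal gland and structures that line the third ventricle of the adult rat brain. The circumventricular organs examined were the pineal gland, which secretes melatonin, the subcommissural organ, a gland of tall ependymal cells in the roof of the ventricle that secretes into the cerebrospinal fluid, and the subfornical organ, which senses blood-borne signals of body fluid balance. The ordinary ependyma of the third ventricle and a pool of total brain served for comparison. There were 2 arrays of the pineal gland and 1 of each other tissue. Between 35006 and 35052 of the 35129 probes had a value on each array. The 75th percentile of intensity was 5.78 and 4.90 on the pineal gland arrays, 6.04 for the subcommissural organ, 6.31 for the subfornical organ, 5.77 for the ependyma and 7.93 for total brain.

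The pair of pineal gland arrays gave the only measure of spread. Of the hormone enzyme genes, Asmt was at 80.4 and 72.4, Aanat at 10.9 and 10.7, and Tph1 at 547 and 352. Of 8553 measured genes, 245 (2.86%) differed at least 4-fold between the arrays, 149 higher on the first and 96 on the second. The count was 26 with a filter at the 75th percentile and 439 without a filter. The standard deviation of the log2 difference was 0.77 over all measured genes, 1.15 for genes with a mean level under the pooled median, 0.78 for those up to the 75th percentile and 0.52 above it. The first array was higher by a median of 0.43. For 4604 genes with a mean at or above the pooled 75th percentile the offset was 0.45, with 82.6% higher on the first array, and 0.12 with 59.8% after quantile normalization. Across 9966 genes, which are not independent replicates, the pair correlated with r = 0.94 (rho = 0.96), against 0.85 for the subcommissural organ with the ependyma, 0.84 for the subfornical organ with the ependyma and 0.79 for the subcommissural with the subfornical organ. The pineal gland arrays correlated with those of the other tissues at r between 0.72 and 0.76.

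**Figure D1:**
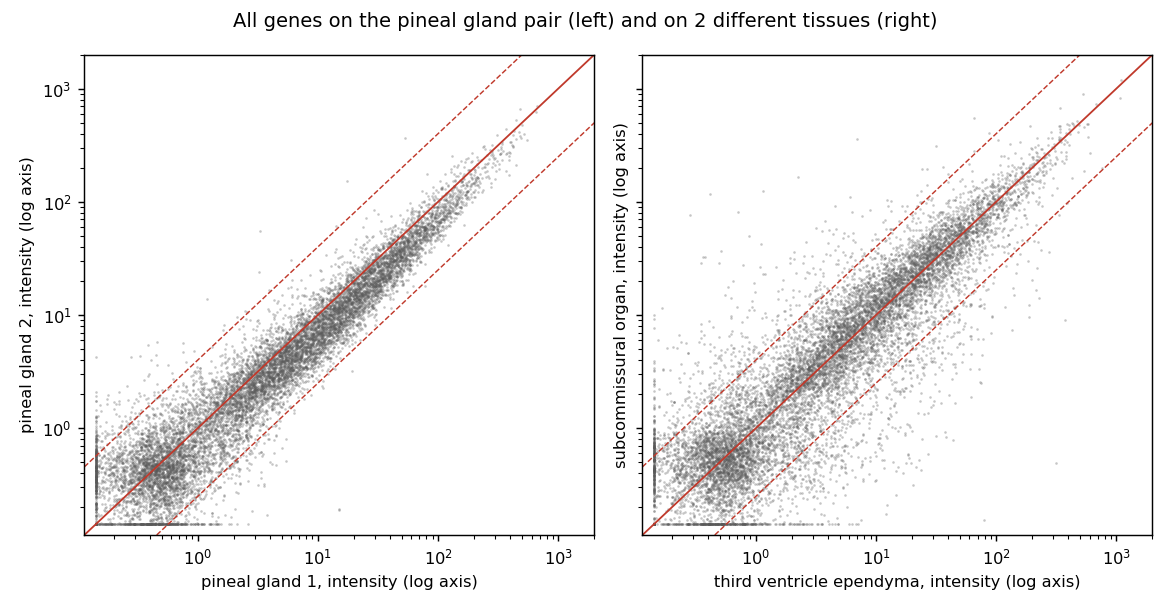
Intensity of every gene on the 2 pineal gland arrays (left) and on the ependyma and subcommissural organ arrays (right), both on log axes, with each point a gene, values below the floor of 0.142 drawn at the floor, the solid line at equality and dashed lines at 4-fold. The pineal gland pair held 245 measured genes beyond 4-fold and the other pair 1134, and points scattered most below an intensity of about 1.05 in both.

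The pineal gland was set against total brain to find what its cells express beyond brain tissue at large. By limma 5 of 8 genes of melatonin synthesis and 16 of 19 of phototransduction rose, while most markers of neurons, oligodendrocytes, astrocytes and motile cilia fell. Tph1, which makes the rate-limiting step of serotonin synthesis, was at 449 ± 138 (SD, n = 2) against 1.91 in total brain, a 230-fold difference. Asmt, which completes melatonin, was at 76.4 ± 5.67 (SD, n = 2) against 0.159, at least 72.6-fold higher. Mog, a myelin protein of oligodendrocytes, was at 0.546 ± 0.222 (SD, n = 2) against 285, at least 271-fold lower.

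All 8 genes of melatonin and serotonin synthesis were measured, with a median log2 difference of 3.06, and 5 rose in limma, with the same 5 when adjusted over the list alone. Ddc, the decarboxylase that forms serotonin, rose 16.1-fold. Aanat, which drives the nightly rhythm of melatonin, rose by a log2 difference of 2.11 by limma, with 10.9 and 10.7 on its arrays. It was named after its values were seen. Gch1, which supplies the cofactor of tryptophan hydroxylase, lay near background in total brain and was at least 3.79-fold higher. Of 19 measured phototransduction genes, 16 rose and none fell, over all genes and adjusted over the list alone, with a median of 5.97. With genes near background set at the bound, the melatonin median was 2.02 and that of phototransduction stayed at 5.97. Pdc, which binds G protein subunits in photoreceptors, was at 324 ± 96.0 (SD, n = 2) against 0.586, at least 301-fold higher. The transducin subunit Gngt1 was 341-fold higher, Gnat2 at least 238-fold and the cone phosphodiesterase gene Pde6c at least 112-fold. Prph2, a structural protein of photoreceptor discs, was at least 297-fold higher and Mpp4, a scaffold at photoreceptor synapses, at least 266-fold. Both stood outside the list. Keratins Krt15 and Krt19 were at least 97.7-fold and 252-fold higher, and the fatty acid binding protein Fabp12 at least 213-fold.

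Pineal transcription factors had a median of 3.13 over 9 genes, and 5 rose (5 also adjusted over the list alone), with a median of 1.63 when genes near background were set at the bound. Pax4 stood at 131 and 124 against 0.797, Otx2, needed for the gland to form, was 8.93-fold higher and Mitf 9.18-fold. Neurod1 was at least 6.60-fold higher. Genes of the adrenergic and cAMP response went both ways, with a median of -1.19 over 8 genes. In limma 2 rose and 3 fell, and 2 and 4 adjusted over the list alone. Crem, whose product turns off cAMP-driven transcription, was at least 2.30-fold higher, while the clock gene Per1 was at least 3.58-fold lower. The marker list of the habenula had 5 measured genes and a median of -1.63. Its nicotinic receptor genes Chrna3 and Chrnb4 were 53.7-fold and 47.1-fold higher, while Tac1 and Calb2 fell, 2 genes in each direction by limma and 2 and 3 adjusted over the list alone. That median turned to 0.68 without a filter on low values and to 0.03 with the stricter filter.

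The fall of other cell types covered 13 of 14 oligodendrocyte genes, with a median of -4.99, 9 of 11 astrocyte genes with -3.90, and 9 of 12 neuron genes with -5.15, the same counts adjusted over the list alone. The 1 neuron gene that rose was Slc17a7, a vesicular glutamate transporter, at 14.0 and 12.3 against 3.13, named after its values were seen. With genes near background at the bound the medians were -4.39 for oligodendrocytes and -3.57 for neurons. Gfap, the astrocyte filament, stood at 0.553 and 0.568 against 28.4, and the glutamate receptor subunit Grin1 at 0.435 and 0.931 against 151. Of 14 motile cilia genes 10 fell (11 adjusted over the list alone), with a median of -2.94 (-2.66 with genes near background at the bound). Blood-brain barrier genes fell for 8 of 11 and rose for 1, with a median of -3.54 (9 and 1 adjusted over the list alone) and -2.22 at the bound. The 1 that rose was the amino acid transporter gene Slc7a5, by 2.98 on the log2 scale, named after its values were seen. The tight junction gene Cldn5 was 14.6-fold lower and the transporter gene Mfsd2a at least 10.3-fold lower. The endothelium list itself had a median of -0.54 over 10 genes, with Emcn higher and none lower by limma in either adjustment. Body fluid and hormone receptors had a median of -1.34 over 17 genes, with 2 higher and 6 lower (8 lower adjusted over the list alone). The sodium channel Scn7a was at least 12.4-fold higher.

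Lists with smaller shifts were microglia and macrophages, at a median of -0.74 over 13 genes with 5 lower (6 adjusted over the list alone), choroid plexus, at -0.70 over 12 genes with 3 higher and 2 lower (3 and 3), and mural cells and fibroblasts, at 0.45 over 12 genes with 2 in each direction (3 and 2). Among choroid plexus genes, the clotting factor F5 was at least 31.8-fold higher, and Ttr, which carries thyroid hormone, was at 104 and 152 against 116, named after its values were seen. Immediate early and stress genes had a median of -0.70 over 7 genes with Dusp1 lower (0 adjusted over the list alone), and the 8 housekeeping genes 0.35 with 0 called in either adjustment. Medians of the roof plate list (-0.43, 4 genes, -0.23 at the bound), the endoplasmic reticulum list (-0.31, 19 genes) and the tanycyte list (-0.41, 4 genes) had no stable side, since quantile normalization moved them to 0.14, 0.00 and 0.12. Calls in these lists, the same adjusted over the list alone, were Pax6 higher and Msx2 lower for the roof plate, Canx lower for the endoplasmic reticulum, and Col23a1 higher and Crym lower for tanycytes.

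Of 9071 measured genes, 1900 (20.9%) differed at least 4-fold, 609 higher and 1291 lower in the pineal gland. With values under the bound set at it, 1400 of the 1900 stayed at 4-fold. By limma 2160 genes passed, 696 higher and 1464 lower, and 3005 had an unadjusted p under 0.05. Without the filter, where the spread differed between genes, limma called 991, while 2008 genes were at 4-fold. The filter at the 75th percentile left 1234 genes at 4-fold. The median of all genes was -0.45 with the deposited values and 0.03 after quantile normalization, which changed the 4-fold split from 32.1% higher to 44.8% (790 higher and 973 lower) and the limma calls to 583 higher and 646 lower.

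**Figure D2:**
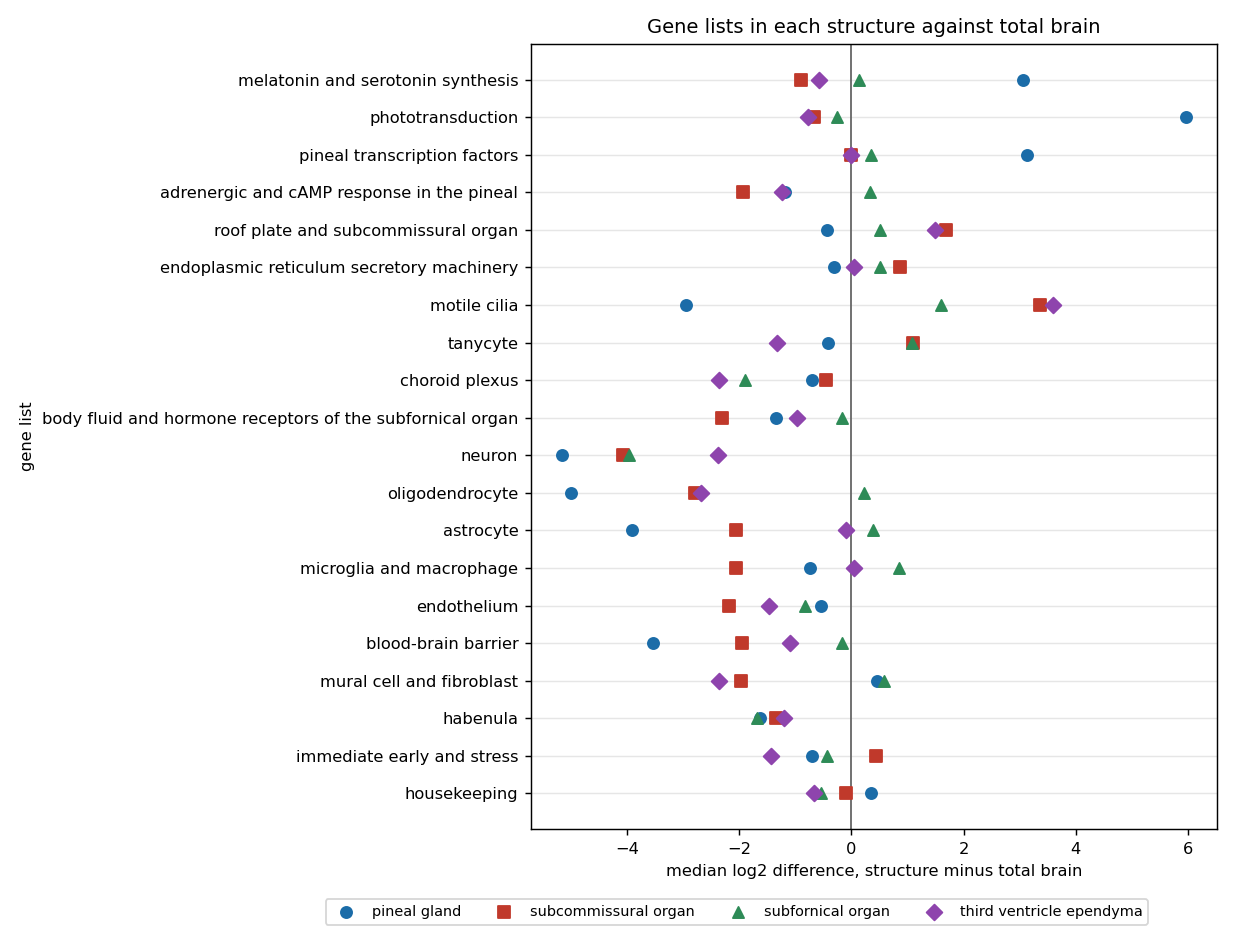
Median log2 difference of each gene list (vertical axis) in the pineal gland, subcommissural organ, subfornical organ and ependyma against total brain (horizontal axis, log2), with 1 symbol per structure. Phototransduction genes stood at 5.97 in the pineal gland, and motile cilia genes at 3.36 and 3.59 in the subcommissural organ and ependyma but at -2.94 in the pineal gland.

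The subcommissural organ was set against total brain with 1 array on each side, as were the subfornical organ and the ependyma, so these differences have no replicate check of their own, and no p-value is given for them. Genes of motile cilia were higher in the subcommissural organ, the secretory machinery had a median above 0, and markers of neurons, glia and vessels were lower. Cuzd1, a zona pellucida domain protein, stood at 116 against 0.370, at least 110-fold higher. Creb3l4, a membrane-bound transcription factor of secretory cells, was at least 72.7-fold higher, the small Maf factor Mafk at least 77.6-fold, and Hsd11b2, which inactivates glucocorticoids, at least 34.8-fold.

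Of 16 measured motile cilia genes 15 were at least 4-fold higher, with a median of 3.36. The dynein light chain gene Dynlrb2 was at 490 against 13.8, 35.6-fold higher, the tektin gene Tekt1 30.3-fold, Mlf1 25.7-fold and Cfap126 21.7-fold. Outside the lists, Efcab10, Ttll9 and Enkd1 were at least 69.6-fold, 15.4-fold and 98.3-fold higher. Endoplasmic reticulum genes had a median of 0.88 over 19 genes, at the 99.8th percentile of random lists, with 5 at least 4-fold higher and 1 lower. Creld2, which responds to stress of that organelle, was at 37.8 against 3.78 and the translocon subunit Sec61b 5.11-fold higher, whereas the chaperone Canx was at least 9.06-fold lower. The roof plate list had a median of 1.69 over 6 genes (0.95 with genes near background at the bound). Pax6 stood at 26.7 against 0.373, at least 25.4-fold higher, and Msx1 at 241 against 33.3, 7.25-fold higher. Both act in the dorsal midline of the embryo. Nes and Vim, intermediate filament genes of the tanycyte list, were 5.33-fold and 4.62-fold higher, with a list median of 1.10 that was -0.0030 without the filter.

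Neuron markers had a median of -4.08, with 11 of 12 at least 4-fold lower, and oligodendrocyte markers -2.79, with 12 of 14 lower. Thy1 was at 11.9 against 509 and Mag was 8.64-fold lower. Astrocyte genes had a median of -2.06 (6 of 11 lower), microglia and macrophage genes -2.05 (7 of 13), endothelial genes -2.19 (7 of 10) and mural cell and fibroblast genes -1.97 (5 of 10). Body fluid and hormone receptors stood at -2.31 (-1.09 at the bound), with 8 of 15 lower, including Ramp2 at 10.4-fold lower. Choroid plexus genes split, 4 higher and 4 lower of 11. Ttr was 72.2-fold lower, and Calml4 and Kcne2 were 14.2-fold and 6.85-fold higher. Immediate early genes split as well, with Egr1 13.5-fold and Fos 12.6-fold lower while Nr4a1, named after its values were seen, was at 43.1 against 19.9. Atg101, an autophagy factor, was at least 70.5-fold higher, with a level of 0.744 on the total brain array and between 54.1 and 74.1 on all other arrays.

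Of 9113 measured genes, 2140 (23.5%) differed at least 4-fold, 786 higher and 1354 lower. With values under the bound set at it, 1595 of the 2140 stayed at 4-fold. The pineal gland pair differed that much in 2.86% of genes. The median of all genes was -0.29, and 0.01 after quantile normalization, which changed the 4-fold split to 904 higher and 1123 lower. A filter at the 75th percentile left 1411 genes.

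The subfornical organ differed less from total brain than the subcommissural organ did in the count at 4-fold. All measured neuron genes were at least 4-fold lower, and the median of cilia genes was higher. Oligodendrocyte genes stood near the level of total brain. Crygs, a lens crystallin, was at 139 against 0.661, at least 132-fold higher. Ifi27l2b, an interferon-induced gene, was at 179 against 1.08, 165-fold higher. Svil, an actin-binding protein of membranes, was at least 23.3-fold higher, Itgb4, a laminin receptor subunit, at least 74.8-fold, and Pdlim3 at least 53.0-fold.

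Neuron markers were lower for all 12 measured genes, with a median of -3.96. Slc17a6, the vesicular glutamate transporter, stood at 6.26 against 161 and the neurofilament gene Nefl at 1.80 against 38.6. Fibcd1, an acetyl group receptor, was at least 134-fold lower here and in the subcommissural organ and the pineal gland. Motile cilia genes had a median of 1.59, with 5 of 16 at least 4-fold higher, led by Dynlrb2 at 11.4-fold and Tekt1 at 7.45-fold. Microglia and macrophage genes had a median of 0.85 over 13 genes, at the 99.6th percentile. The lysosomal protein gene Cd68 was 4.79-fold higher and the adaptor Tyrobp 3.00-fold. Astrocyte genes had a median of 0.39 over 12 genes (0.16 at the bound). Gfap was at 140 against 28.4, 4.93-fold higher. The 14 oligodendrocyte genes had a median of 0.23 with none beyond 4-fold, Ugt8 at 1.77-fold higher and Opalin at 2.49-fold lower.

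Body fluid and hormone receptors had a median of -0.16 over 16 genes, which turned to 0.13 after quantile normalization. Scn7a, the sodium channel tied to sodium sensing, was at least 3.24-fold higher, and the angiotensin receptor gene Agtr1a stood at 1.96 against 5.33, named after its values were seen. Ramp3, a partner of the calcitonin receptor family, was at least 8.58-fold lower. Mural cell and fibroblast genes had a median of 0.59 (0.15 at the bound), with Ogn at least 8.61-fold higher and Rgs5 at least 4.92-fold lower. Endothelial genes had a median of -0.82 over 10 genes, and Plvap, which marks fenestrated vessels, stood at 3.36 against 13.0. Choroid plexus genes had a median of -1.89 (-0.84 at the bound), with 5 of 11 lower. Six6, a factor of the hypothalamic tanycyte list, was at least 5.42-fold higher and Crem at least 7.45-fold.

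Of 9166 measured genes, 1542 (16.8%) differed at least 4-fold, 659 higher and 883 lower. With values under the bound set at it, 1042 of the 1542 stayed at 4-fold. The median of all genes was -0.20, and 0.06 after quantile normalization, which changed the 4-fold split to 726 higher and 729 lower. A filter at the 75th percentile left 866 genes.

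The ependyma of the third ventricle had high levels of motile cilia genes. Oxt, which encodes oxytocin, was at 317 against 0.535 in total brain, at least 302-fold higher. Among cilia genes, 15 of 17 were at least 4-fold higher with a median of 3.59. Dynlrb2 was at 574, 41.7-fold higher, Tekt1 36.9-fold and Mlf1 28.3-fold. Outside the lists, Ccdc33, Lrrc36 and Ttll9 were at least 58.7-fold, 47.0-fold and 17.4-fold higher, and the calcium pump gene Atp2c2 at least 50.3-fold.

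Markers of neurons had a median of -2.38 in the ependyma, with 9 of 12 lower, and those of oligodendrocytes -2.68, with 12 of 14 lower. Sox10, a factor of the oligodendrocyte lineage, was at least 8.64-fold lower and Ermn 8.93-fold. Astrocyte genes lay at -0.10 over 12 genes and 0.19 after quantile normalization, and microglia and macrophage genes at 0.04 over 13. Mural cell and fibroblast genes had a median of -2.35, with 6 of 11 lower and 1 higher. Tagln, a smooth muscle protein, was at least 3.25-fold lower and the collagen-binding Dcn 7.13-fold. Endothelial genes stood at -1.47 and blood-brain barrier genes at -1.08, with Mfsd2a 8.05-fold lower. The receptor genes Npy1r and Agtr1a were at least 21.4-fold and 5.07-fold lower, whereas Ramp1, a partner of the receptor for calcitonin gene-related peptide, was 5.11-fold higher. Msx1 was 6.13-fold higher, with a roof plate median of 1.49 over 4 genes (0.88 at the bound). Immediate early and stress genes had a median of -1.42 over 6 genes, with Nr4a1 5.02-fold lower. Choroid plexus genes had a median of -2.36, with 2 higher and 6 lower of 11, which was -0.84 at the bound and turned to 0.29 at the 75th percentile filter. The tanycyte list stood at -1.33 over 4 genes and turned to 0.20 at that filter.

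Of 9103 measured genes, 1522 (16.7%) differed at least 4-fold, 672 higher and 850 lower, and 877 with a filter at the 75th percentile. With values under the bound set at it, 1020 of the 1522 stayed at 4-fold. After quantile normalization the majority turned, with 778 higher and 598 lower, that is 56.5% higher in place of 44.2%. The median of all genes moved from -0.41 to -0.06.

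Set against ependyma rather than total brain, the pineal gland again had higher melatonin and phototransduction genes and lower cilia genes, and limma was run as against total brain. Of 17 motile cilia genes all 17 fell, also adjusted over the list alone, with a median of -5.69 (-5.41 at the bound). Dynlrb2 stood at 0.387 and 1.84 against 574, at least 546-fold lower, Cfap126 was at least 180-fold lower, and Hydin, a protein of the central pair of the axoneme, 179-fold. Outside the lists, T2 and Spag6l were at least 194-fold and 110-fold lower. Phototransduction genes had a median of 7.04 over 19 genes (6.18 at the bound), with 15 higher and 1 lower (16 and 1 adjusted over the list alone). Gngt1 was at least 462-fold higher, Pdc at least 301-fold, the arrestin gene Sag at least 321-fold and Rgs9 at least 178-fold. The melatonin list had a median of 3.03 (2.11 at the bound) with 5 of 8 higher in both adjustments, among them Tph1 at least 417-fold and Asmt at least 72.6-fold. Pineal transcription factors had a median of 3.25 (2.72 at the bound), and 6 of 9 rose in both adjustments.

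Astrocyte genes fell for 8 of 12 (10 adjusted over the list alone) with a median of -3.43, and oligodendrocyte genes for 8 of 12 (9) with -2.34. Aqp4, the water channel of astrocytes, was 72.2-fold lower. Neuron genes had a median of -2.30 over 11 genes (-1.03 at the bound), with 1 higher and 7 lower (2 and 7 adjusted over the list alone), and the vesicular transporter gene Slc17a7 was at least 12.5-fold higher in the gland. Microglia and macrophage genes had a median of -1.48 with 1 higher and 5 lower (2 and 6), and Cd68 was at least 10.7-fold higher. Mural cell and fibroblast genes were at 2.22 (1.59 at the bound), with 7 of 12 higher in both adjustments, among them Dcn at 24.3-fold and Mgp at 6.74-fold. Endothelial genes were at 0.90, with 2 of 10 higher in both adjustments. Plvap was 4.97-fold higher and Cldn5 6.28-fold lower. Choroid plexus genes had a median of 2.47 over 9 genes, with 5 higher and 2 lower (5 and 3), Kcne2 at least 42.9-fold and Ttr 25.3-fold higher. The collagen gene Col8a1 was at least 238-fold higher.

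Of 8961 measured genes, 1623 (18.1%) differed at least 4-fold, 582 higher and 1041 lower in the gland, and 1030 with the filter at the 75th percentile. With values under the bound set at it, 1184 of the 1623 stayed at 4-fold. By limma 1809 passed, 649 higher and 1160 lower, and 2514 had an unadjusted p under 0.05. Quantile normalization lowered the limma calls to 1124, and dropping the filter lowered them to 724. In these settings the spread differed between genes, and the counts at 4-fold were 1644 and 1745.

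**Figure D3:**
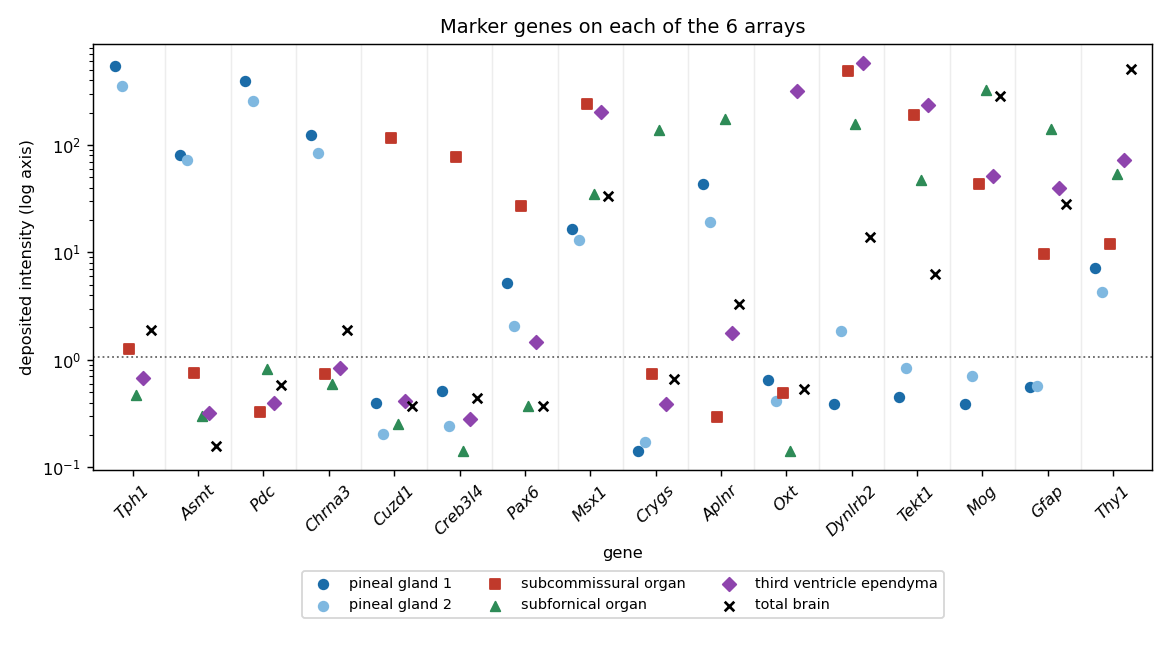
Deposited intensity (log axis) of 16 named genes on each of the 6 arrays, with values below 0.142 drawn at that floor and the dotted line at 1.05, the bound used for folds. Tph1, Asmt and Pdc stood high on both pineal gland arrays, Cuzd1 on the subcommissural organ array, Crygs on the subfornical organ array and Oxt on the ependyma array.

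The subcommissural organ and the ordinary ependyma are both ciliated walls of the ventricle, and the comparison asked what sets the organ apart. Cilia genes differed little, with a median of -0.23 over 17 genes and none beyond 4-fold. Endoplasmic reticulum genes were higher, with a median of 1.03 over 20 genes that lay above all 10000 random lists, although 1 alone was 4-fold higher and 1 lower. Lcn2, an iron-carrier binding protein of the acute phase, was at 124 against 1.15, 108-fold higher. Cuzd1, Mafk and Creb3l4 were at least 110-fold, 77.6-fold and 72.7-fold higher, as against total brain. Gpha2, a glycoprotein hormone subunit, was at least 30.9-fold higher and Ftcd, an enzyme of histidine breakdown, 72.8-fold.

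Pax6 was 18.2-fold higher and Otx2 5.24-fold, in a list of pineal transcription factors with a median of 2.26 over 5 genes (0.75 at the bound) that was -0.30 without the filter. Nes was 15.0-fold higher, and the potassium channel genes Kcnj13 and Kcne2 at least 27.1-fold and 27.7-fold. Both channels belong to the choroid plexus list, which had a median of 0.06 over 8 genes, with 4 above 0 and 4 below. Of these, 3 were at least 4-fold higher and 0 lower. Sdf2l1, a chaperone partner in the endoplasmic reticulum, was 3.38-fold higher and Creb3l2 at least 3.07-fold. Astrocyte genes had a median of -1.93, with 6 of 12 lower, and microglia and macrophage genes -1.96 at the bound, with 7 of 13 lower. The gap junction gene Gja1 was 13.0-fold lower and Tyrobp 9.46-fold. Neuron genes had a median of -2.14 (-1.49 at the bound), with 5 of 10 lower, while oligodendrocyte genes stood at -0.22. Oxt was at least 302-fold lower, Vip, which encodes vasoactive intestinal peptide, at least 14.0-fold, and the chemokine gene Ccl17 at least 75.7-fold. Immediate early genes went both ways. Nr4a1 was 10.9-fold higher, and Egr1 and Fos were 5.72-fold and 4.11-fold lower. Of 8885 measured genes, 1134 (12.8%) differed at least 4-fold, 436 higher and 698 lower. A filter at the 75th percentile left 567 and a floor at the 50th percentile 693.

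The subfornical organ exceeded the ependyma in oligodendrocyte and mural cell genes and lay below it in cilia genes. Oligodendrocyte genes had a median of 2.83, with 12 of 14 at least 4-fold higher. Mobp was at 195 against 25.5, 7.65-fold higher, and Fa2h 9.58-fold. Mural cell and fibroblast genes had a median of 2.31, with 7 of 12 higher, including Tagln at least 11.1-fold and Dcn 11.9-fold. Motile cilia genes had a median of -2.03, with 9 of 17 lower, among them Tekt2 at 19.2 against 185, 9.63-fold lower.

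Crygs was at least 132-fold higher, and Aplnr, the apelin receptor, stood at 173 against 1.78, 97.3-fold higher. Rgs19 was 62.6-fold higher, and the extracellular matrix genes Pcolce and Nid2 were 61.9-fold and at least 34.1-fold higher. The macrophage lectin gene Clec10a was at least 55.7-fold higher and Cd68 at least 24.6-fold, in a microglia and macrophage list with a median of 0.64. Body fluid and hormone receptors had a median of 0.87 over 14 genes, with 3 higher and 2 lower. Scn7a was at least 3.24-fold higher, the angiotensin-converting enzyme gene Ace 7.10-fold, Agtr1a at least 1.86-fold, and Ramp3 at least 3.27-fold lower. The amino acid transporter gene Slc38a5 was 10.2-fold higher and Mfsd2a 7.15-fold in the blood-brain barrier list, whose median was 0.53. Neuron genes had a median of -1.48 over 10 genes (-1.02 at the bound), with 3 lower, and Slc17a6 was 7.16-fold lower. Oxt was at least 302-fold lower, and, outside the lists, Spef2 and Fsip1 at least 21.6-fold and 20.4-fold. Of 9048 measured genes, 1211 (13.4%) differed at least 4-fold, 613 higher and 598 lower, and 620 with the filter at the 75th percentile or 781 with the floor at the 50th.

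Genes that marked a structure were those at least 4-fold above each of the other tissues. In the pineal gland Gngt1 exceeded the next tissue by 312-fold, Pdc by at least 244-fold, Fabp12 by at least 203-fold, Tph1 by 185-fold and Gnat2 by 136-fold. Miox, an enzyme of inositol breakdown, exceeded it by 121-fold and the photoreceptor kinase gene Grk1 by at least 54.8-fold. There were 100 such genes among 7599 measured, and 120 without the first pineal gland array and 154 without the second, since the lower of both arrays no longer had to pass.

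The subcommissural organ had 57 such genes among 8039. Beyond those already named, they included Tmigd1 at 23.7-fold, the cadherin-family gene Cdhr5 at least 11.3-fold, the epithelial adhesion gene Epcam at least 8.97-fold and Galnt3, which starts mucin-type glycosylation, at least 14.3-fold. Gfra1, the receptor for glial cell line-derived neurotrophic factor, was at 361 against 22.9 in the next tissue, 15.7-fold higher. The subfornical organ had 75 among 8318 (48 with the filter at the 75th percentile). They included Kiss1, which encodes kisspeptin, at least 17.7-fold, the growth factor gene Fgf3 at 11.2-fold, Cbs, an enzyme of sulphur amino acids, at 11.1-fold, the cartilage matrix gene Ucma at least 11.9-fold and the homeobox gene Vax1 at 8.71-fold. The ependyma had 53 among 8261, and 35 with that filter. Besides Oxt they included Npvf, which encodes a neuropeptide of the hypothalamus, at least 17.1-fold, the serum amyloid gene Apcs at least 15.8-fold, Ccl17 at 23.4-fold, the cone phosphodiesterase gene Pde6h at 18.6-fold, the slow troponin gene Tnnt1 at 14.5-fold and the heparan sulphate proteoglycan gene Gpc3 at 9.34-fold.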

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

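Of the tests here, those of general neuron transcripts, of a lower share of ependymal cells and of fibre tract tissue were chosen only after the result was seen. Against total brain, motile cilia genes moved in opposite directions in the pineal gland, with a median of -2.94, and in each ciliated wall. The gap was 6.30 to the subcommissural organ, 4.54 to the subfornical organ and 6.53 to the ependyma, in log2 units. The tanycyte list, also in opposite directions against total brain, was at 1.10 in the subcommissural organ (4 genes), 1.09 in the subfornical organ (6 genes, 0.66 at the bound) and -1.33 in the ependyma (4 genes), with gaps to the ependyma of 2.43 and 2.42. Set directly against the ependyma, its medians were smaller, 0.67 (4 genes) and 1.02 (6 genes, 0.52 at the bound). None of these opposite directions was tested, and the tanycyte list turned to -0.0030 in the subcommissural organ without a filter and to 0.20 in the ependyma with the 75th percentile filter. Among 18167 probes that no single gene symbol names, and that entered no comparison, 115 were at least 4-fold above every other tissue in the pineal gland, 85 in the subcommissural organ, 68 in the subfornical organ and 55 in the ependyma.

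The ependyma array held high levels of Oxt (317), Hcrt (188), Npvf (17.9) and Vip (14.7). Neuronal RNA from the adjoining hypothalamus is a candidate source, since 11 other measured neuropeptide genes had a median 1.95 above the mean of both organs, at percentile 100 of matched random lists, although Pdyn (-1.35) and Crh (-0.45) lay below it, and Gal and Adcyap1 were higher in the subfornical organ and Penk in the subcommissural organ than in the ependyma. The median is the value of Pmch, at 1.93 in the ependyma against 0.361 in the subcommissural and 0.687 in the subfornical organ, both under the bound. Ghrh too was under it in both organs, so the size and rank of the median rest in part on background values. None of the 11 was on another list, and 8 reached the bound in the subfornical organ, 6 in the subcommissural organ and 9 in total brain. General neuron transcripts (10 genes) were likewise higher by a median of 1.68, at percentile 99.98. The median lies between Nefl and Nefm, and Nefm was under the bound in both organs, so its size is not exact. Gad1 was higher in the subfornical organ and Grin1 in the subcommissural organ than in the ependyma. Slc17a6 and Camk2a were at least 4-fold above both organs. Syn2, at 2.30 against 0.438 and 0.304, was so only in values under the bound, against which 4-fold is not shown. A single faulty spot cannot have raised all 4 genes, which have 1 probe each and were picked for their height, but for any 1 of them it cannot be told apart, since 0 of 16 other neuropeptides on the array were 4-fold above both organs, and a difference of the ependyma itself stays open and untested.

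Oligodendrocyte genes were higher in the subfornical organ than in the ependyma. A lower share of ependymal cells would raise all other cell types alike only if these kept the same proportions to each other. Proportions were not measured apart from these lists, whose medians did not move alike. The mural cell and fibroblast list, left out of the test as set, did lie within 0.51 of the oligodendrocyte median, less than the spread of 0.83 among the 14 oligodendrocyte genes. The neuron list, also left out, was lower in the organ, at -1.48 over 10 genes (-1.02 at the bound). The highest of the astrocyte, microglia and endothelium medians lay 2.19 below the oligodendrocyte median, more than the spread within any of these lists (0.88, 1.36 and 1.52). This argues against a lower ependymal share with kept proportions as the whole cause, while a part of the rise from it stays open. For a lower share together with changed proportions the gap cannot decide. Fibre tract tissue caught with the organ may add to it and cannot be told apart from oligodendrocytes of the organ, since the median lay 0.23 above total brain, between the bounds set for either, and a difference between the tissues themselves was not tested. None of the 14 genes was on another list, and 14 reached the bound in the subfornical organ, 13 in the subcommissural organ and 14 in total brain.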

How the results depend on the processing

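The floor at the 50th percentile was the only alternative here chosen after the data were seen. Of 70 list medians of at least 1 in size, 68 moved by less than the spread of the pineal gland pair after quantile normalization. That spread was 0.54 per array and is one of single genes. Another 2 moved by more on the same side and 0 reversed. The largest median shift of an array was -0.34, in total brain, so a reversal of medians this large was unlikely from the start. Of all 140 list medians 12 changed sign, none of them above 0.43 in size. Of 662 differences of named genes, 647 moved by less than that spread and 15 by more under quantile normalization, and 528 and 134 with the mean of a gene's probes. A gene with 1 probe could not move with that mean, and how many of the named genes had several was not counted. The 528 therefore do not measure how well probes agree. A change of side was counted as a reversal only for genes at 4-fold or more, where there were 0 in both settings. Smaller differences that changed side are within these counts. With the mean of probes, which again could shift only genes with several probes, 55 list medians moved by less, 15 by more and 0 reversed. The 20th percentile floor gave 66, 4 and 0, the 50th percentile floor 45, 25 and 0, the 75th percentile filter 51, 14 and 5, and no filter 35, 31 and 4. Low signal over background limits the weak genes most. No paired analysis was possible because the pineal gland was the only group with more than 1 array. Without 1 of its arrays no residual degree of freedom is left, so limma gave no test.

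With the filter at the 75th percentile, which leaves fewer genes, 4-fold counts against total brain were 1234 in the pineal gland, 1411 in the subcommissural organ, 866 in the subfornical organ and 877 in the ependyma. Against the ependyma they were 1030, 567 and 620, for the pineal gland, subcommissural and subfornical organ. Genes above every other tissue numbered 48 in the subfornical organ and 35 in the ependyma, and 26 differed between the pineal gland arrays. At 2-fold, a wider limit by construction, the counts were 4183, 4478, 3865 and 4114 against total brain and 3516, 2874 and 3347 against the ependyma, in the same orders. Genes 2-fold above every other tissue numbered 250 in the pineal gland, 271 in the subcommissural organ, 339 in the subfornical organ and 179 in the ependyma, and 1724 differed between the pineal gland arrays. With the floor at the 50th percentile, which shrinks differences of weak genes, the counts were 693 for the subcommissural and 781 for the subfornical organ against the ependyma, and 48 between the pineal gland arrays. With no filter, 439 genes differed between these arrays, and limma called 991 against total brain and 724 against the ependyma. After quantile normalization limma called 1229 and 1124. Limma over all 6 arrays called 722 genes between the subfornical organ and ependyma. Leaving out each pineal gland array gave 120 to 154 genes above every other tissue.

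Reversed list medians, for which the cause was not tested, were these. Against total brain they were the habenula list in the pineal gland (0.68 with no filter, 0.033 at the 75th percentile), tanycytes in the subcommissural organ (-0.0030 with no filter), and choroid plexus and tanycytes in the ependyma (0.29 and 0.20 at the 75th percentile). Against the ependyma they were immediate early and stress genes (-2.04 at the 75th percentile) and pineal transcription factors (-0.30 with no filter) in the subcommissural organ, and melatonin genes in the subfornical organ (-0.0255 with no filter, -0.0510 at the 75th percentile).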

Other observations

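The levels of Penk, Gal and Slc17a6 and the share of the ependyma level were singled out only after the results were seen, and no test was added for them, while the cilia list was fixed before the data were examined. Penk, which encodes the enkephalin precursor, stood at 205 and 149 on the pineal gland arrays, against 46.9 in total brain and 13.5 in the ependyma. Gal, which encodes galanin, was at 20.3 and 10.1 in the pineal gland, 54.2 in the subfornical organ and 45.8 in the ependyma. It was at 5.26 in total brain and 1.67 in the subcommissural organ. The vesicular glutamate transporter gene Slc17a6 was at 94.1 and 53.5 in the pineal gland, against 161 in total brain and 44.8 in the ependyma. Grin1, a glutamate receptor gene, was at 0.435 and 0.931 in the gland, against 151 and 26.4 in these tissues. Motile cilia genes in the subfornical organ stood at a median of 24.5% of their ependyma level, with a median log2 difference of -2.03 and a standard deviation of 0.69 over 17 genes.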
